A study of Bos taurus with 12 samples.

How the data were processed

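RNA was measured in 12 libraries from single cattle blastocysts collected at day 7.5, of which 5 lacked exon 1 of OCT4 and 7 were controls. Per the labels' protocols, each embryo was lysed and its lysate divided between a pair of tubes, total RNA was extracted with TRIzol, cDNA was amplified by a modified mcSCRB-seq protocol, and amplified cDNA entered an Illumina tagmentation library preparation with dual indexes. HISAT2 2.2.1, SAMtools 1.17 and featureCounts 2.0.1 and the genome build ARS-UCD1.2 (bosTau9) are named in the submitters' processing notes. The annotation release, the strand setting of the counting and any use of molecular identifiers are not given in the sources used here. Reads of overlapping, antisense or near-identical genes are therefore uncertain.

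The deposited file holds raw counts, whole numbers of reads per gene that the authors had not normalised, for 27607 Ensembl identifiers in 12 columns. All 12 columns were matched to a sample by name, and groups were taken from the genotype label. The labels treat the embryos as separate samples but name no sire, sex, culture batch or collection day, and do not say whether controls were electroporated. The p-values therefore measure the spread between these embryos, amplification noise included, and handling and genotype are not separated. The gene tests share the dispersion of each gene between both groups, although edited embryos differed more from each other than wild-type embryos did. What this does to the p-values was not tested. No pair of libraries agreed within sampling noise (lowest chi-square per degree of freedom of any pair 7.6), so none was a library deposited again. Amplification adds noise beyond counting, so this comparison does not show that libraries came from separate embryos, which rests on the labels and the series design.

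The reference gene table used here (assembly ARS-UCD2.0 of RefSeq) matched 0 of the identifiers to a symbol. The 23 gene lists fixed beforehand, the count of POU5F1, the test of genes on its chromosome, and the shares of ribosomal protein and mitochondrial genes were therefore not run. The planned rule for named genes, the genes with a symbol and the largest changes past the threshold at 10 CPM or more in the higher group, named none for the same reason. In its place the pair of genes with the smallest p in each direction, at 10 CPM or more in the higher group, is printed, a choice made after the values were seen.

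Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr, robust dispersions, glmQLFit with robust = TRUE and this version's default deviances, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment at 0.05 and group as the only term. The filter left 11926 genes over all 12 embryos and 12308 without edited embryo 2, and the common dispersions were 0.201 and 0.151. CPM are TMM-scaled, and log2 CPM used a prior count of 2. Fold changes are edited over wild type. Each SE of a log2 fold change was derived as its absolute value divided by the square root of the quasi-likelihood F, and is not a separately fitted error. The design fixed beforehand did not say which form of the quasi-likelihood deviances to use. The default form was run first, a draft then used the bias-adjusted form, and the default was restored, so the bias-adjusted form is given as an alternative chosen after seeing the data. Single values per embryo were compared by exact permutation over all splits of 12 embryos into 5 and 7, and Benjamini-Hochberg adjustment covered the 4 embryo-level tests. The test of total reads was added to this family after the data were examined. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for these tests and the figures.

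Libraries held 168974 to 4781663 reads. Against these unscaled totals 3 reads equal 17.8 CPM in edited embryo 2, 3.86 in edited embryo 5 and 2.03 in edited embryo 4. In wild type they equal 0.627 to 1.09 CPM. On the TMM scale used for expression values, 3 reads were 18.4 CPM in edited embryo 2 and 2.45 CPM in edited embryo 4. Because amplified reads were counted and collapsing of molecules is not stated, floors and 95% Wilson intervals cover counting error only.

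The test was checked on simulated counts with the real means and library sizes. Over all 12 embryos it called 7 of 99 genes changed 2-fold, 69 of 97 changed 4-fold and 3 of 11483 unchanged genes. Without edited embryo 2 it called 26 of 97, 66 of 96 and 4 of 11790. In each simulated gene both groups had the same dispersion. The wider spread between edited than between wild-type embryos was thus not simulated, and these rates may not hold for the real data.

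The alternatives chosen before the data were examined were RLE, upper quartile and library-size scaling, DESeq2 1.42.0, limma 3.58.1 voom with sample quality weights, no filter, at least 10 CPM in 5 libraries, log2 library size or 1 surrogate variable (sva 3.50.0) as a covariate, thinning to the smallest total, leaving out the 50 most abundant genes, other thresholds, and leaving out each embryo. Alternatives to the comparison without edited embryo 2, including the omission of edited embryos 4 and 5, were chosen after seeing the data, and so were the comparison of the omitted embryo with genes not called, weighted to the same deciles of wild-type level, the thinned version of the spread between embryos and the omission of each embryo from the library measures.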

Results

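Gene expression was measured by RNA sequencing in 12 single cattle (Bos taurus) blastocysts produced in vitro and collected at day 7.5. In 5 of them exon 1 of OCT4 had been deleted, and 7 were wild-type controls. OCT4, encoded by POU5F1, is a POU-family transcription factor of pluripotent cells. The editing method delivered CRISPR-Cas systems against DNA and RNA by double electroporation, and the comparison addresses what loss of OCT4 function does to gene expression in the blastocyst. Each library was made from part of an embryo's lysate after amplification of its cDNA. The count table listed 27607 genes by Ensembl identifier, of which 22163 had at least 1 read. No table used here paired these identifiers with gene symbols, so genes are given by identifier and the count of OCT4 itself is not given, which leaves the genotype labels unchecked by expression.

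On average, edited blastocysts gave shallower and less even libraries than wild-type blastocysts. Total reads assigned to genes were 1754826 ± 1376187 in edited embryos (SD, n = 5) and 3577889 ± 635156 in wild type (SD, n = 7; two-sided exact permutation test over all splits of the embryos into 5 and 7, p = 0.0177). Single wild-type libraries held 2762133 to 4781663 reads. Edited embryos 1 and 3 lay within that range, with 3202922 and 3145326 reads, whereas edited embryos 4, 5 and 2 had 1478796, 778114 and 168974 reads. After every library was thinned to 168974 reads, 9890 ± 2211 genes (SD, n = 5) were detected in edited embryos and 11594 ± 187 (SD, n = 7) in wild type (two-sided exact permutation test, p = 0.0126). Edited embryo 2 had 6084 detected genes, and without it the difference was -753 in place of -1704 genes (exact p = 0.0303). The 50 most abundant genes took 24.9% ± 7.05 of reads in edited embryos (SD, n = 5) and 16.1% ± 1.01 in wild type (SD, n = 7; exact permutation p = 0.00505). Edited embryo 1 lay within the wild-type range on both measures, with 11560 genes and a share of 17.2%. With the spread between embryos given last, these were 4 embryo-level tests, and the highest Benjamini-Hochberg adjusted p among them was 0.0177.

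**Figure D1:**
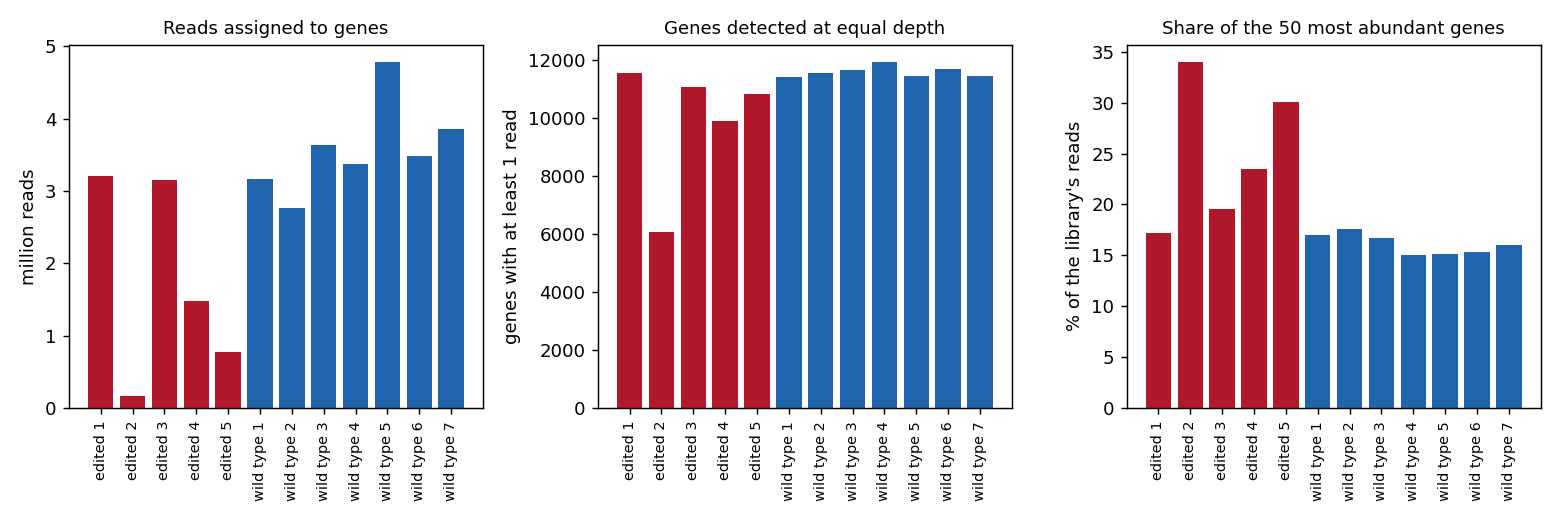
Bars give, for each of the 5 edited (red) and 7 wild-type (blue) libraries, the reads assigned to genes, the genes with at least 1 read at 168974 reads, and the percentage of reads in the 50 most abundant genes. Edited embryo 2 has 6084 genes at equal depth against 11415 to 11939 in wild type, and its top genes hold 34.0% of its reads.

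Over all 12 embryos, 3 of 11926 tested genes rose in edited blastocysts and 0 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The rises were 3.8-fold to 8.55-fold, and in all 3 genes every edited embryo lay above every wild-type embryo. ENSBTAG00000045249 rose from 3.07 ± 1.05 CPM in wild type (read counts scaled to library size; SD, n = 7) to 28.0 ± 12.4 CPM in edited embryos (SD, n = 5), a log2 fold change of 3.10 (SE 0.403, edgeR adjusted p = 0.00633). ENSBTAG00000018077 rose from 19.7 ± 6.26 to 105.6 ± 60.7 CPM, a log2 fold change of 2.35 (SE 0.365, edgeR adjusted p = 0.0349). In edited embryo 2 the value of ENSBTAG00000045249, 49.1 CPM and the highest of the edited embryos, rested on 8 reads. No gene passed the test for lower expression. Of those nearest to it, ENSBTAG00000014118 had 27.9 ± 3.64 CPM in wild type and 3.79 ± 3.75 CPM in edited embryos, a log2 fold change of -2.46 (SE 0.439, edgeR adjusted p = 0.0536). Edited embryo 2 had 0 reads of this gene, at a depth where 3 reads equal 18.4 CPM. ENSBTAG00000010131 had 112.8 ± 22.5 CPM in wild type and 32.5 ± 14.7 CPM in edited embryos, a log2 fold change of -1.70 (SE 0.308, edgeR adjusted p = 0.0536). In both of these genes all 5 edited embryos lay below the lowest wild-type embryo. Both passed the threshold over all 12 embryos under upper quartile scaling (edgeR adjusted p = 0.0409), library size alone (0.0481), DESeq2, voom with quality weights, no filter, 1 surrogate variable and bias-adjusted deviances, and neither did under RLE scaling (0.0587), the 10 CPM filter, log2 library size as a covariate or without the 50 most abundant genes. At an unadjusted p under 0.05 the same test gave 886 genes with higher and 915 with lower values in edited embryos, where chance alone gives about 596 in all, and DESeq2 called 354 higher and 369 lower. Scaling by upper quartile gave 15 higher and 7 lower calls, and scaling by library size alone 3 higher and 6 lower, with the median log2 fold change of all tested genes at -0.278 in place of -0.05.

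**Figure D2:**
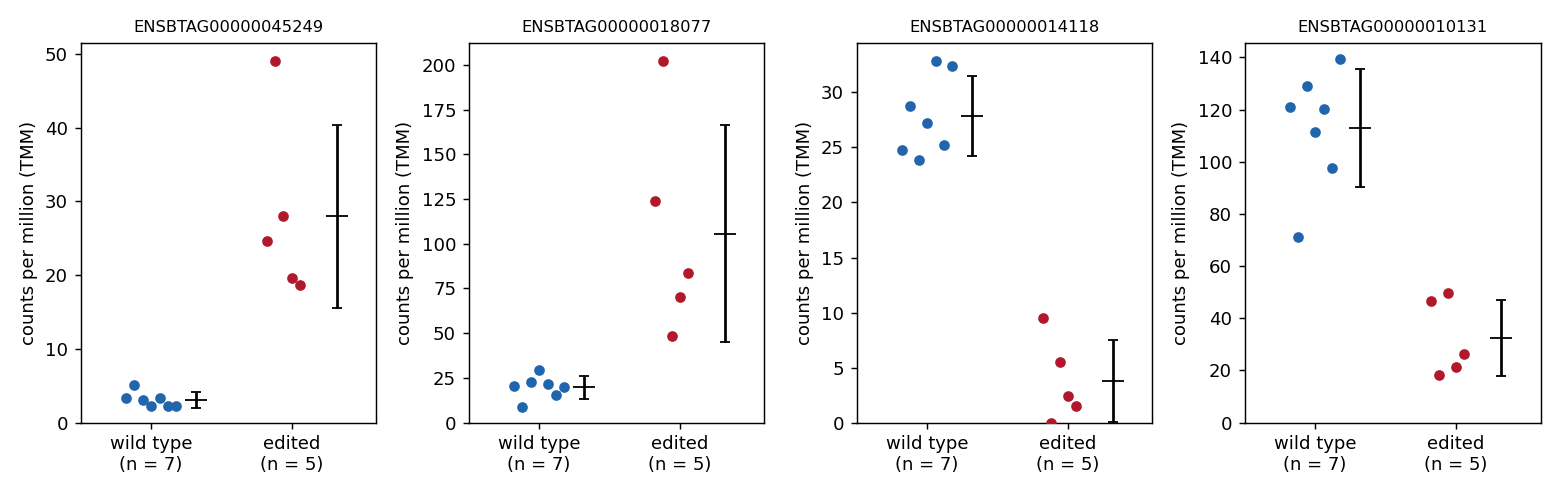
Points are the TMM-scaled CPM of 4 genes in each of 7 wild-type (blue) and 5 edited (red) embryos, and the bars beside them are the mean ± SD. Both genes on the left rose in edited embryos, and both on the right lay lower in every edited embryo at an adjusted p of 0.0536.

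The call of ENSBTAG00000045249 held when each of the 12 embryos was left out in turn, with adjusted p at most 0.0348. That of ENSBTAG00000018077 was lost without edited embryo 5 (adjusted p = 0.0579) and without wild-type embryos 1, 2, 3, 5, 6 or 7 (adjusted p = 0.0717 to 0.11 in the edgeR fits). ENSBTAG00000014118 passed the threshold without edited embryo 1 or 2 (adjusted p = 0.0215 and 0.00734), and ENSBTAG00000010131 without edited embryo 1, 2 or 3 (adjusted p = 0.0389, 0.00734 and 0.0409). The number of called genes became 58 without edited embryo 1, 652 without edited embryo 2, 32 without edited embryo 3, 2 without edited embryo 4, and 1 without edited embryo 5 or without wild-type embryo 1, 2, 3, 5, 6 or 7.

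Edited embryo 2, the shallowest library, is the one whose removal moved the result most. Its removal was among the planned checks, but its result is described on its own only because its size was seen. In the other 11 embryos, 451 of 12308 tested genes rose and 201 fell (edgeR quasi-likelihood test, adjusted p under 0.05), and DESeq2 called 880 higher and 708 lower. Leaving out 1 further embryo took the 652 calls to 339 without edited embryo 4 and to 328, 305, 369 and 316 without wild-type embryos 1, 3, 5 and 7. The genes that rose had a median log2 fold change of 1.11 (quartiles 0.86 and 1.44), and 275 of them rose at least 2-fold. They took 22.7% of reads in edited and 10.8% in wild-type embryos. The 2 most abundant of them held 7.98% and 3.29%, with 15.4% in edited embryo 5 and 3.89% in edited embryo 1, and without these the shares were 14.7% and 7.49%. The genes that fell had a median log2 fold change of -1.28 (quartiles -1.90 and -0.94), and 137 of them fell at least 2-fold. Among them, 2 genes had 0 reads in all 4 edited embryos, and setting these at a floor of 3 reads over the group left the median at -1.28. Summed in the same way, the TMM-scaled CPM of the 201 genes came to 0.9% in edited and 1.87% in wild-type embryos. All 4 edited embryos lay above all 7 wild-type embryos in 258 of the genes that rose, and below them in 169 of those that fell. Over all tested genes such separation occurred in 3.08% upward and 3.42% downward, against 0.303% by chance in each direction. That chance share is an average over all splits of exchangeable embryos. Genes are not independent and this share was not computed for other splits, so the contrast is not a test. ENSBTAG00000045249 and ENSBTAG00000018077 were among the genes that rose, with log2 fold changes of 2.88 (SE 0.362) and 2.03 (SE 0.294) and edgeR adjusted p of 0.00245 and 0.00373. ENSBTAG00000014118 and ENSBTAG00000010131 were among those that fell, at -2.37 (SE 0.381) and -1.61 (SE 0.263), both with an edgeR adjusted p of 0.00734. With log2 library size as a covariate ENSBTAG00000010131 lost this call (log2 fold change -1.19, edgeR adjusted p = 0.063), and ENSBTAG00000014118 kept it (adjusted p = 0.0438). The omitted edited embryo 2 lay above the wild-type median in 25.5% of the 451 genes, against 25.6% of genes not called and of matched wild-type level, and below it in 83.1% of the 201 genes, against 74.7% of such genes. These shares were not tested, and 33.5% of the 451 and 48.8% of the 201 genes had 0 reads in that library.

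The share of genes called was higher among abundant than among scarce genes, as is the power of a count test, and the difference was not tested. Without edited embryo 2, 17 of 86 genes above 1000 CPM rose and 0 fell, and under scaling by library size alone 10 rose and 1 fell. Between 100 and 1000 CPM 195 of 2034 genes rose and 45 fell, between 10 and 100 CPM 213 of 7376 rose and 130 fell, and below 10 CPM 26 of 2812 rose and 26 fell. Scaling by library size alone turned the balance in these classes to 69 higher and 151 lower, 88 higher and 344 lower, and 17 higher and 46 lower. Over all classes that scaling gave 184 higher and 542 lower calls, of which 385 were among the 652, and it moved the median log2 fold change of all tested genes to -0.246 from -0.03. With log2 library size as a covariate 62 genes were called, 59 higher and 3 lower, which included 52 of the 451 and 2 of the 201 genes, and the median log2 fold changes of the 451 and the 201 genes were 0.995 and -1.09 (median SE 0.288 and 0.353 in place of 0.243 and 0.303). With edited embryos 4 and 5 left out as well 221 were called, 163 of them among the 652.

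**Figure D3:**
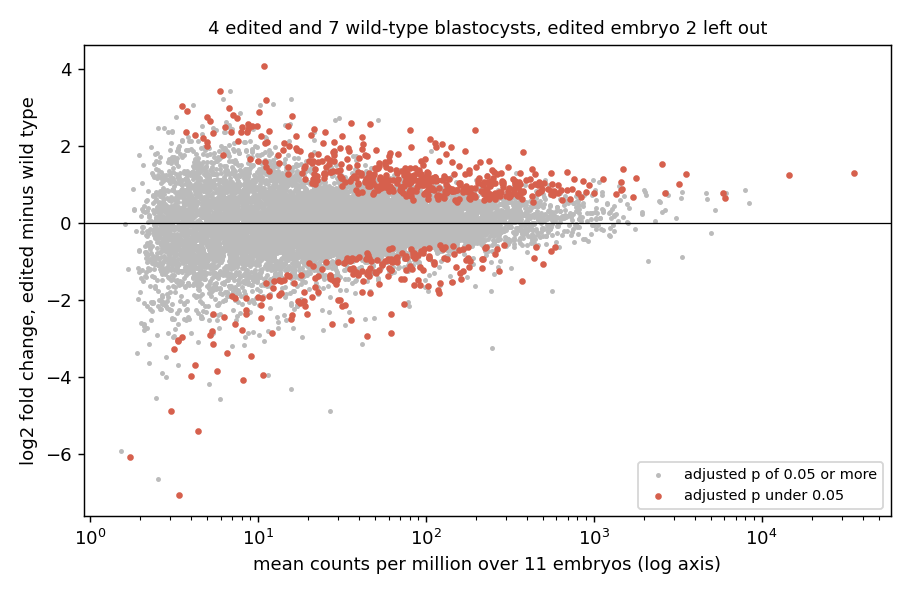
Each point is 1 of 12308 tested genes in 4 edited and 7 wild-type embryos, with its mean CPM on a log axis and its log2 fold change, edited minus wild type, on the other. Red points are the 451 genes that rose and 201 that fell under TMM scaling, and under library size alone the split was 184 and 542.

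Edited embryos differed more from each other than wild-type embryos did. The mean Euclidean distance between log2 CPM profiles was 250.7 over pairs of the 5 edited embryos and 82.9 over pairs of the 7 wild-type embryos, and the difference of 167.8 was as large in 8 of the splits into 5 and 7 embryos (two-sided exact permutation p = 0.0101). Edited embryo 2 had Spearman correlations across genes of 0.529 to 0.586 with the other 11 embryos. Pairs among the other 4 edited embryos lay between 0.781 and 0.923, and wild-type pairs between 0.89 and 0.956. Pairs of those 4 with wild-type embryos lay between 0.796 and 0.92, with a median of 0.862 against 0.851 among the 4. Without edited embryo 2 the mean distance in edited embryos was 149.0 and the difference 66.1 (exact permutation p = 0.0424), and with all 12 libraries thinned to the smallest total the difference was 51.4 (exact permutation p = 0.00884).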

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

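Tests chosen only after the result was seen were those of depth alone for edited embryo 2, of shallow libraries, of low-yield libraries (whose converse had been seen) and of a few abundant genes for the 652 genes, and the measure that singled out edited embryo 2, which was added after a first pass over the other 14 groups of values had singled out none.

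Edited embryo 2 stood apart from the other edited embryos in its median Spearman correlation with the other 11 libraries, 0.568, where its gap to the next embryo was 0.728 of the range of the 5 edited embryos against a critical value of 0.71. It was the 1 group singled out among 16 tested, and chance singles out about 1 in 20. Depth alone is argued against, since 18.58% of the 3380 genes expected at 10 or more reads from the other edited embryos had 0 reads (Wilson 95% interval 17.3 to 19.9), against at most 0.552% in any other library thinned to the same total. A large change shared with the other edited embryos is also argued against. Of the 3911 genes expected at 10 or more reads from the wild-type embryos, 778 had 0 reads in edited embryo 2. In edited embryos 1, 3, 4 and 5 these 778 had a median log2 fold change of -0.054 (bootstrap 95% interval -0.092 to -0.018). The other 3133 genes, with reads in edited embryo 2, had a median of 0.027 there, so a small shared change is not excluded. Amplification from few starting molecules stays open and may account for the pattern, as 7.253% of genes expected at 2 to 5 reads had at least 4 times that number, against at most 1.712% elsewhere, and whether such loss of RNA came from handling or from the embryo itself was not tested.

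The 652 genes called without edited embryo 2 exceeded every other division tried. Of 100 splits of those 11 embryos, 1, the real one, gave as many, and the highest other gave 3. Chance is thus argued against but not excluded, as only 100 of 330 possible splits were run. Edited embryo 2 was also set apart because its removal gave the most calls, a choice that the splits did not repeat. Shallow libraries as the whole cause are argued against by edited embryos 1 and 3, which lie within the wild-type range of depth. They gave 221 calls against the 7 wild-type embryos, and the highest of the other choices among 36 gave 6. At equal depth edited embryo 3 nevertheless had 11079 genes, against 11415 to 11939 in wild type. Its 50 most abundant genes took 19.6% of reads, against 15.1% to 17.6% in wild type. Library quality other than depth is thus not separated from genotype and remains open. Low-yield libraries 4 and 5 as the whole cause are argued against, because 82.2% of the 500 genes chosen in them (88.4% under the other assignment of controls) had the same sign in edited embryos 1 and 3 against other controls, where 63.2% and 66.1% of all genes did. Leaving out the 50 most abundant genes left 609 calls but moved the median log2 fold change of all genes only from -0.026 to -0.038, so it does not decide whether a few abundant genes contribute, and scaling by library size alone turned the balance to 184 higher and 542 lower. Loss of OCT4 and differences in handling remain open and untested, as does a part played by depth, which goes with the group. With log2 library size as a covariate 62 genes were called, while 450 of the 451 rises and all 201 falls had the same sign. The 652 genes were chosen in the same counts, so the kept signs were likely in advance and do not weigh against a part played by depth. The median log2 fold changes of 0.995 and -1.09, in place of 1.11 and -1.28, had wider errors (median SE 0.288 and 0.353, in place of 0.243 and 0.303). Folds lay nearer 0 in 269 of the 451 and 164 of the 201 genes.

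The greater distance between edited embryos is not explained by depth alone, as the difference without edited embryo 2 was 39.21 at a common depth of 778114 reads (122.5 against 83.3, exact permutation p = 0.0455). Low-yield libraries may account for it, since edited embryos 1 and 3 lay 91.34 apart, within the 73.5 to 100.2 of wild-type pairs, of which 4 of 21 were as large, whereas pairs with edited embryo 4 or 5 lay 119.4 to 149.9 apart. A biological difference between edited embryos, such as in the extent of editing, was not tested.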

How the results depend on the processing

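All alternatives to the 652 genes, and the bias-adjusted form among those to the 3 genes, were chosen after seeing the data. For the 3 genes called over all 12 embryos, RLE scaling, the 10 CPM filter, leaving out the 50 most abundant genes and a minimum of 2-fold again gave 3. Upper quartile scaling gave 22, library size alone 9, DESeq2 723, voom with quality weights 426 (weight of edited embryo 2, 0.192), no filter 40, log2 library size as a covariate 33, 1 surrogate variable 240, adjusted p under 0.1 gave 191 and under 0.01 gave 1, and bias-adjusted deviances gave 193. All 3 genes were among the calls in each of these except at 0.01. Thinning to the smallest total gave 0 with edgeR, with 590 of 4245 genes at an unadjusted p under 0.05 and fewer genes tested. Leaving out each embryo gave 1 to 652. Causes of the other changes were not tested. Of 100 splits of the 12 embryos, 1 gave 3 or more calls, the real one, and the highest other gave 1, a narrow margin. The simulated data gave 3 calls of unchanged genes, but beside 7 and 69 calls of genes changed 2-fold and 4-fold. That count is therefore not a rate of false calls among the 3 real ones. For the 652 genes, DESeq2 gave 1588, log2 library size as a covariate 62, edited embryos 2, 4 and 5 left out 221, and leaving out each other embryo 305 to 757, with 339 without edited embryo 4 and 328, 305, 369 and 316 without wild-type embryos 1, 3, 5 and 7. The other settings gave 601 to 776. The differences in genes detected at equal depth, in the share of the 50 most abundant genes and in the spread between embryos kept their direction and their side of the threshold in every alternative run, and total reads had none. The gene lists, POU5F1 and chromosome alternatives were not run, for want of symbols. Depth limits edited embryo 2 most, where 3 reads equal 18.4 CPM.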

Other observations

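The tests here were chosen after the data were examined. The direction of change was compared between edited embryos 1 and 3 and the shallower edited embryos 4 and 5, without edited embryo 2. Separate wild-type controls were assigned to the pairs in both ways. Of the 500 genes with the smallest p in edited embryos 1 and 3, 85.4% and 92.8% had the same sign in edited embryos 4 and 5. Among all genes compared, 63.2% and 66.1% had the same sign. Across genes, which are not independent replicates, the fold changes of the pairs had Pearson r of 0.347 and 0.388.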
